A study of Mus musculus with 12 samples.

How the data were processed

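Skin was flash-frozen and RNA extracted with Trizol, and libraries were made with oligo-dT beads and the Illumina TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name Bowtie2 and RSEM; their versions and roles, the genome build and the annotation are not given in the sources used here, so genes are named by the symbol and NCBI gene ID of the deposited table and no coordinates are printed. The strand setting is not given either. The deposited gene table gives 18858 genes. Its expected counts (estimated reads per gene) were made by the authors before deposit, with tools that include Bowtie2 and RSEM per the submitters' processing notes. Only these counts were used, and the table's other columns were not. Of the expected counts 88.7% were whole numbers as deposited (a tolerance of 0), and all were rounded to whole numbers. The deposited transcript table was not used here. No row lacked a gene symbol.

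Columns were given to samples by their codes. The PBS and TL+L codes carry the sample numbers of the labels. The codes TS and TSL were read as TSeL and TSeL+L, because TSL adds an L to TS as the label TSeL+L does to TSeL; this is a reading of the codes, and every value of TSeL and TSeL+L depends on it. The 3 TSeL columns share the number 2 and the 3 TSeL+L columns the number 1, and 2 columns of each add a suffix that the labels do not explain, so no column was given to a single labelled sample. Within each group, pairs of columns were compared by a chi-square over genes with at least 40 counts in the pair. The TSeL and the TSeL+L columns differed far less than PBS or TL+L samples did and close to counting noise, with mean chi-squares of 1.19 to 1.41 and 1.38 to 1.49 against 25.1 to 59.0 in PBS and 60.9 to 184 in TL+L. The 3 columns of each were averaged and counted as 1 sample. The planned fit took all 12 columns as separate samples; the fit of 8 samples was chosen after seeing the data, and the planned one is given as an alternative.

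Genes were filtered with filterByExpr, which left 15791, and tested with edgeR 4.0.16 in R 4.3.3 by a robust quasi-likelihood F-test with TMM factors and 1 coefficient per group. The TMM factors ran from 0.852 in TSeL to 1.10 in TL+L replicate 1, and the common biological coefficient of variation was 0.278. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All tests were two-sided. A permutation of 3 against 3 samples cannot give a p under 0.1. CPM values use the TMM factors, and log2 CPM a prior count of 2.

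Before the data were examined, 49 gene lists were fixed, with 971 genes, of which 953 were matched to the table by symbol, or by NCBI gene ID and synonym, and 18 were not. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with adjustment over the lists, and again with a correlation estimated from the 4 residual degrees of freedom; no call held with the latter. Genes were named by a rule fixed at the same time. It took the 6 largest rises and 6 largest falls among called genes without a predicted-gene symbol, with at least 5 CPM in the higher group and no overlap between groups, or the 3 smallest p in a direction where none passed. It added up to 3 members of up to 6 leading lists, and any of 20 panel genes that passed. Lists named elsewhere are given as lists. Genes with 0 to 3 counts in a group are given with counts and an exact (Clopper-Pearson) 95% interval, or as a bound against a floor of 3 counts in the sample.

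The test was run on simulated counts with 200 changed genes in each of 5 draws over 15791 genes. Genes were drawn independently with the fitted spread, and the 200 changed genes lay outside the lists, with at least 5 CPM in PBS. Each draw also shifted the measured genes of the chemokine list by -1.5 (log2). Calls of these chemokine genes are part of all calls below, and they were not counted as unchanged genes. No sample was made to stand apart from its group, so the shares recovered may be higher than in the real samples. For TL+L against PBS it recovered 36.0% of 2-fold, 96.0% of 4-fold, 97.6% of 8-fold and 98.4% of 16-fold changes, and 7.55% of its calls were unchanged genes, above the 5% aimed at. For TSeL against PBS it recovered 6.40%, 65.6%, 91.2% and 94.0%, with 7.19% of calls unchanged, and for TSeL+L against PBS 6.80%, 76.0%, 92.8% and 95.6%, with 6.59%. For TSeL+L against TL+L these were 8.00%, 71.6%, 91.6% and 95.6%, with 8.20%.

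Alternatives were DESeq2 1.42.0 (Wald test), limma-voom (limma 3.58.1), size factors of the DESeq2 type, library totals, no filter, a stricter filter (at least 10 counts in at least 3 samples and a mean of at least 1 CPM), only the compared groups, a 2-fold minimum, the sample number as a block, leaving out each PBS or TL+L sample, and, for lists, fry. The planned fit of 12 columns became an alternative when the fit of 8 samples was chosen. Chosen after seeing the data were 1 column in place of each average, TMM without hair and muscle genes, leaving out a sample in comparisons without its group, and, for lists, leaving out samples and the fit of the PBS and TL+L samples alone. Figures were drawn with matplotlib.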

Results

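Poly(A) RNA was sequenced from the skin of BALB/C mice, an inbred albino laboratory strain, which the series text gives as 8 weeks old. The labels place 12 samples in 4 groups of 3: PBS (phosphate-buffered saline, the control), TL+L, TSeL and TSeL+L. The labels do not say what TL, TSeL and L stand for, so the groups are named as given. They also do not say that each sample came from a separate animal, so p-values measure the spread between these samples. The 12 deposited columns of estimated gene counts held 16630580 to 17318158 counts each, over 18858 genes, of which 15791 were tested.

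The 3 columns read as TSeL differed from one another by little more than counting noise, and so did the 3 columns read as TSeL+L. The median chi-square between 2 columns was 1.12 to 1.17 times its chance value in TSeL and 1.23 to 1.29 times in TSeL+L, against 7.41 to 13.9 times between PBS samples and 8.89 to 37.5 times between TL+L samples. Each of these sets was therefore averaged and counted as 1 sample. The comparisons rest on 3 PBS, 3 TL+L, 1 TSeL and 1 TSeL+L samples, and the lone samples were assumed to vary like the PBS and TL+L samples, which gave 4 residual degrees of freedom. Values of TSeL and TSeL+L below have no replicates.

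The first principal component of log2 CPM (counts scaled to a common effective library size) held 66.4% of the variance and the second 14.4%. PBS replicate 3 lay at -32.9 on the first component, with the other PBS samples at -71.9 and -79.1. TL+L replicate 2 lay at 9.76, with the other TL+L samples at 85.8 and 87.3. The TSeL sample lay on the PBS side at -60.5 and the TSeL+L sample on the TL+L side at 61.7.

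**Figure D1:**
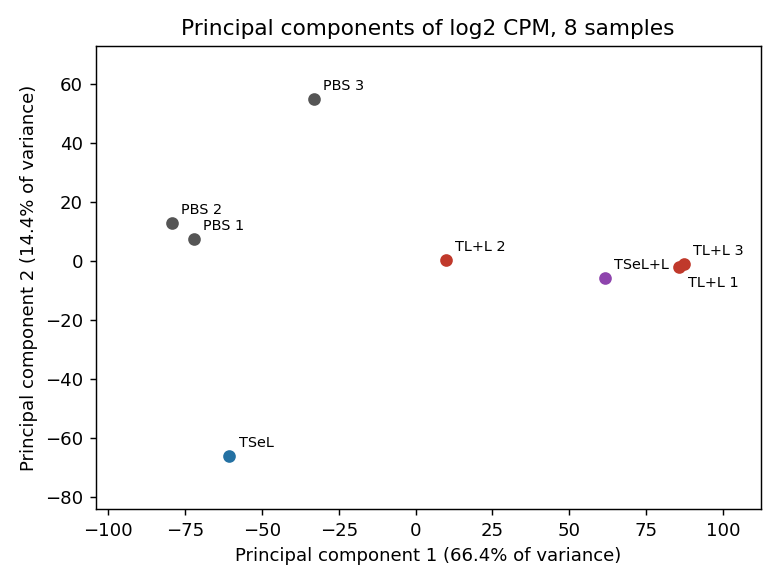
Principal components 1 and 2 of log2 CPM for the 8 samples, with the share of variance on each axis; each point is 1 sample, coloured by group. The TSeL+L sample at 61.7 lies with TL+L on the first component, and TL+L replicate 2 at 9.76 lies between the groups. On the second component the TSeL sample lies apart at -66.0, and PBS replicate 3 at 54.6.

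The comparison of TL+L with PBS asked what the TL+L treatment changed in skin. Transcripts of neutrophils and of inflammatory signalling were lower in TL+L, while transcripts of the hair follicle, sebaceous gland and melanocytes were higher. Hair genes took 0.649% to 5.41% of the counts in the TL+L samples and 0.00395% to 0.234% in the PBS samples. Of 23 measured neutrophil genes, 18 fell over all genes tested and none rose, and 20 fell when adjusted over the list alone; the median log2 fold change was -2.71. Without PBS replicates 1, 2 and 3 the number that fell over all genes tested was 3, 4 and 10, and without TL+L replicates 1, 2 and 3 it was 9, 20 and 7. Trem1 (NCBI gene 58217), an amplifying receptor of myeloid cells, was at 17.8 ± 3.60 CPM in TL+L and 167 ± 21.5 CPM in PBS (SD, n = 3 each), a 9.39-fold fall with an edgeR adjusted p of 0.00535. Of the 23 genes 7 are also in another list. Hdc (15186), which makes histamine and is also in the mast cell list, fell 5.38-fold, and Cxcl2 (20310), a neutrophil-attracting chemokine, fell 8.42-fold. The neutrophil list was lower than other genes by camera (adjusted p = 4.81e-30), but not with an estimated correlation (adjusted p = 0.141 with an estimated correlation).

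Among the 12 named genes with the largest changes, the 6 that fell most included the neutrophil granule gene Ngp (18054), which fell 22.8-fold, and the neutrophil surface marker gene Ly6g (546644), which fell 26.4-fold. Retnlg fell 31.2-fold, from 156 ± 107 CPM in PBS (SD, n = 3). Prl2c3, Prok2 and Chil3 fell 31.8-fold, 29.3-fold and 20.8-fold. Without PBS replicate 1 the folds of Retnlg, Ly6g, Prok2 and Chil3 were 19.3, 16.8, 10.3 and 7.61, and without TL+L replicate 2 those of Ngp, Ly6g and Prl2c3 were 57.1, 58.5 and 83.8. In TL+L the counts were only 1 to 15 per sample for Prl2c3, 2 to 14 for Ly6g and 2 to 9 for Prok2, so their folds are imprecise. Prl2c3 and Ly6g belong to families of near-identical copies whose shared reads make their levels uncertain.

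Cytokine and chemokine genes fell with them. Of 27 chemokine genes 9 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -1.22 (adjusted p = 0.155 with an estimated correlation). Cxcl5 (20311) fell from 272 ± 21.4 to 48.3 ± 8.85 CPM and Cxcl1 (14825) from 101 ± 39.9 to 13.7 ± 1.22 CPM (SD, n = 3 each). Of 20 pro-inflammatory cytokine genes 7 fell and none rose (9 adjusted over the list alone; adjusted p = 0.396 with an estimated correlation). Il6 (16193) fell 17.4-fold, Il1b (16176) 4.74-fold and Tnf (21926) 2.25-fold, with edgeR adjusted p of 0.0134, 0.0120 and 0.0490. Of 24 macrophage and monocyte genes 7 fell and none rose (16 adjusted over the list alone; adjusted p = 0.436 with an estimated correlation). They included Cd14 (12475), the co-receptor for lipopolysaccharide, which fell 7.93-fold, Spp1 (20750), which fell 8.67-fold, and Nos2 (18126), the inducible nitric oxide synthase, which fell 15.2-fold. With 1 sample left out, 2 to 17 chemokine, 0 to 8 cytokine and 1 to 20 macrophage and monocyte genes fell over all genes tested, the most without TL+L replicate 2.

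Genes of matrix turnover, vessels and stroma were also lower. Of 17 matrix degradation genes 9 fell and none rose (12 adjusted over the list alone; adjusted p = 0.141 with an estimated correlation). Plaur, the urokinase receptor, fell 6.64-fold, Timp1, an inhibitor of matrix metalloproteinases, 4.86-fold, and Mmp9, a gelatinase also counted in the neutrophil list, 3.67-fold. Of 17 myofibroblast genes 9 fell and none rose (10 adjusted over the list alone; adjusted p = 0.396 with an estimated correlation). Of 16 blood endothelium genes 8 fell and none rose (13 adjusted over the list alone; adjusted p = 0.520 with an estimated correlation). Of 25 fibroblast collagen and matrix genes 3 fell, and 13 adjusted over the list alone, with a median of -1.19 (adjusted p = 0.591 with an estimated correlation). Hmox1, the inducible heme oxygenase, fell 2.19-fold. With 1 sample left out, 1 to 10 matrix degradation, 0 to 13 myofibroblast, 0 to 16 blood endothelium and 0 to 24 fibroblast genes fell over all genes tested, the most without TL+L replicate 2.

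Hair genes showed the highest folds in the other direction. All 31 measured hair shaft and inner root sheath genes had positive log2 fold changes, with a median of 4.72; 8 rose over all genes tested and 31 adjusted over the list alone (adjusted p = 0.520 with an estimated correlation). PBS replicate 3 stood apart, with a hair list mean of 4.70 log2 CPM against 0.95 and -0.59 in the other PBS samples, and without it the median was 8.08. With 1 sample left out, 0 to 12 hair genes rose over all genes tested, the most without TL+L replicate 2. Lef1 (16842) and Foxn1 (15218), transcription factors of the hair follicle, rose 12.1-fold and 9.58-fold, and Dlx3 (13393) rose 12.5-fold; without PBS replicate 3 the folds of Lef1 and Dlx3 were 20.8 and 21.8. The 6 named genes that rose most were Krtap19-4, Krtap19-1, Krtap19-2, Krtap31-2, Krtap31-1 and Car6. The Krtap genes encode hair keratin-associated proteins and belong to families of near-identical copies, so the level of each is uncertain. All PBS counts of these Krtap genes came from PBS replicate 3. Car6 rose 87.5-fold, which was 258 without PBS replicate 3 and 35.5 without TL+L replicate 3. Krtap19-4 had 2 counts in all PBS samples and 1173 in the TL+L samples, 921 of them in TL+L replicate 3, a ratio of 535 with a 95% exact counting interval of 148 to 4420, which covers counting error only. The hair gene share of counts was 0.649% in TL+L replicate 2, against 2.96% and 5.41% in the other TL+L samples.

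Of 18 sebaceous gland genes 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 1.78 (adjusted p = 0.141 with an estimated correlation). Scd1 (20249), the stearoyl-CoA desaturase, rose from 226 ± 27.4 to 1130.3 ± 147 CPM (SD, n = 3 each), and Elovl6 and Apoc1 rose 4.35-fold and 2.91-fold. Of 12 melanocyte genes 7 rose and none fell (11 adjusted over the list alone; adjusted p = 0.484 with an estimated correlation). All 32 cell cycle genes had positive log2 fold changes, with a median of 0.68, of which 1 rose over all genes tested and 24 adjusted over the list alone (adjusted p = 0.591 with an estimated correlation). The proliferation marker gene Mki67 rose 2.06-fold. In TL+L replicate 2, the TL+L sample with the lowest hair list mean, Mki67 was at 169 CPM, against 289 and 248 CPM in the others. The melanocyte and cell cycle list means were lowest there too, at 4.67 and 4.68 log2 CPM. The other TL+L samples were at 6.21 and 6.14 for melanocytes, and 5.39 and 5.13 for the cell cycle. Whether these rises go with hair level was not tested. With 1 sample left out, 0 to 13 sebaceous gland, 0 to 11 melanocyte and 0 to 27 cell cycle genes rose over all genes tested, the most without TL+L replicate 2.

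By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2029 genes changed between TL+L and PBS, 896 higher and 1133 lower, and 1378 of them by at least 2-fold. With library totals in place of TMM factors the split was 1521 higher and 902 lower, and the median log2 fold change of all genes moved from 0.01 to 0.15. In the comparisons of TSeL with PBS, TSeL+L with PBS and TSeL+L with TSeL the same change moved it from 0.01 to -0.18, from -0.00 to 0.16 and from -0.07 to 0.27. The count was 4064 by DESeq2. The edgeR count moved far with any 1 sample left out. It was 16, 95 and 145 without PBS replicates 1, 2 and 3, and 183, 6299 and 70 without TL+L replicates 1, 2 and 3. Genes at an unadjusted p under 0.05 by edgeR numbered 5731 with all samples. With 1 left out they numbered 3724 to 4444, or 7983 without TL+L replicate 2. Of 34 called genes named by the rule, 6 (Cd14, Cxcl2, Cxcl5, Hdc, Plaur and Trem1) passed with any 1 sample left out and 28 did not. TL+L replicate 2 stood apart from its group in the adipocyte list mean (7.25 against 5.75 and 5.91 log2 CPM), the skeletal muscle list mean (10.2 against 7.95 and 8.91) and the hair list mean (5.98 against 8.34 and 9.11). Camera called 30 of 49 lists, 11 higher and 19 lower, and none with an estimated correlation.

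**Figure D2:**
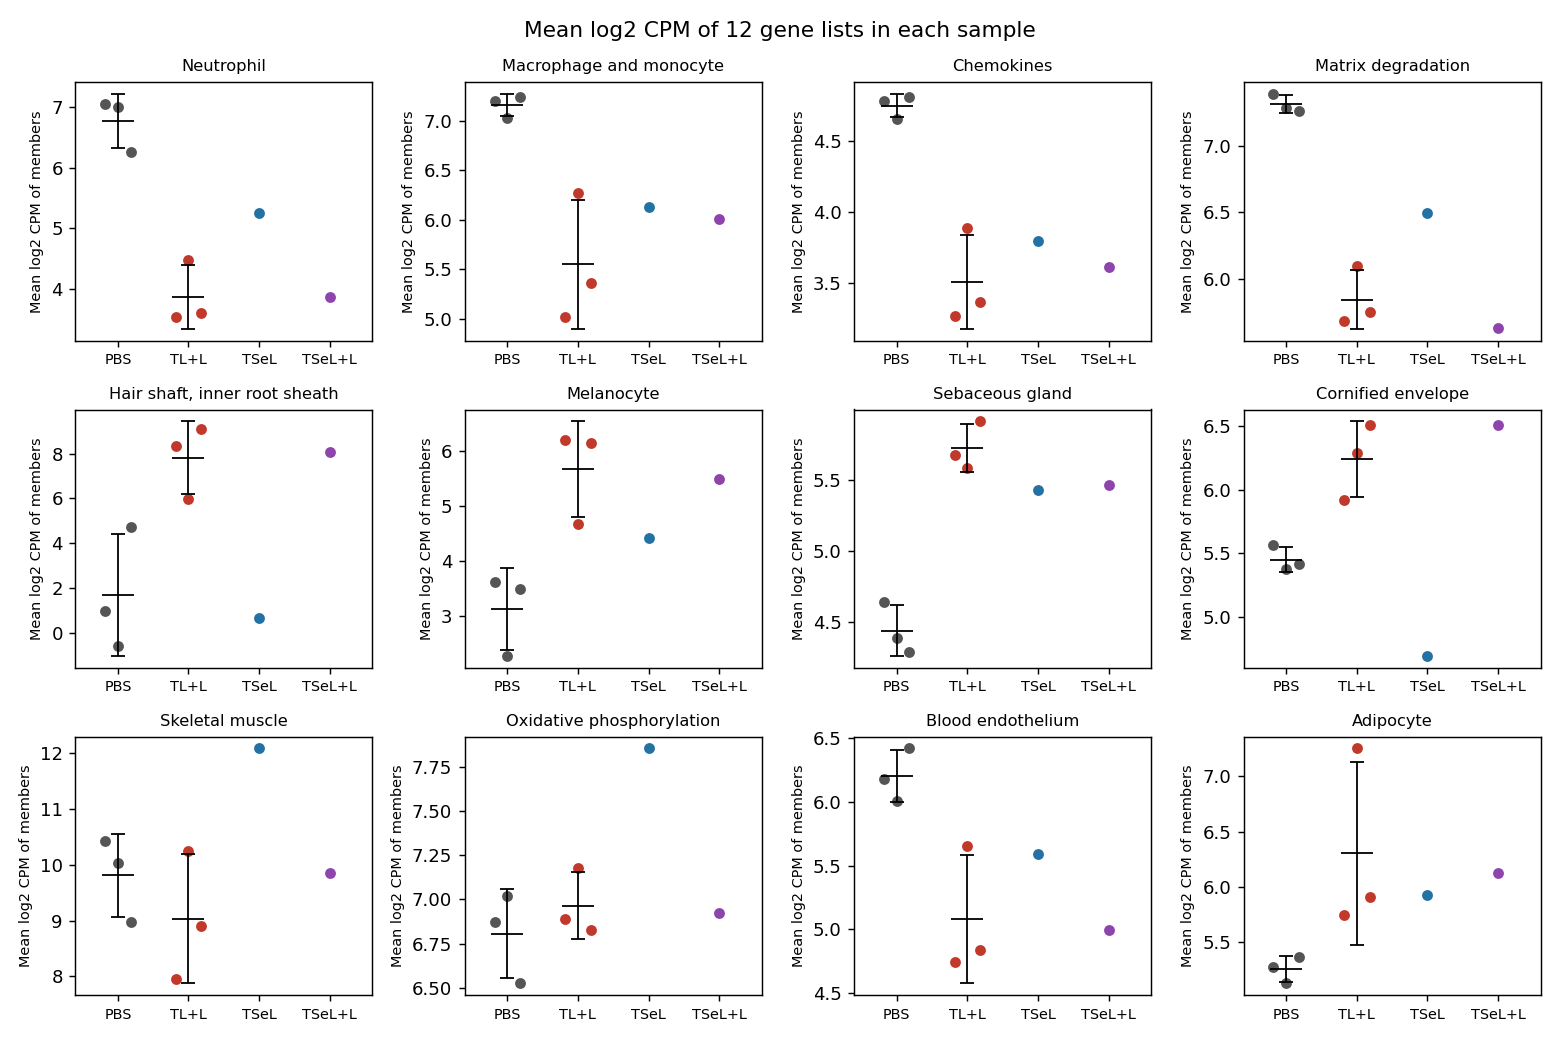
Mean log2 CPM of the measured members of 12 gene lists (vertical axis) in each sample by group (horizontal axis); points are samples, and black bars give the mean and SD of the 3 PBS and 3 TL+L samples. The neutrophil mean is 6.26 to 7.06 in PBS, 3.54 to 4.48 in TL+L, 5.26 in TSeL and 3.87 in TSeL+L, and the skeletal muscle mean is highest in TSeL at 12.1.

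The comparison of TSeL with PBS asked the same of the TSeL treatment, with 1 TSeL sample. Mitochondrial and muscle genes were higher in it than in PBS and neutrophil and mast cell genes lower, but no gene passed the test. All 30 oxidative phosphorylation genes had positive log2 fold changes, with a median of 1.07. None of them passed over all genes tested and 30 did adjusted over the list alone (camera adjusted p = 4.53e-22; adjusted p = 0.451 with an estimated correlation). Cox6c, a subunit of cytochrome c oxidase, was at 290 CPM in TSeL and 135 ± 14.8 CPM in PBS (SD, n = 3), and Uqcrb and Cox7b were 2.19-fold and 1.99-fold higher. All 25 skeletal muscle genes were higher, with a median of 2.18, and none passed either way (adjusted p = 0.455 with an estimated correlation). Ttn, the giant sarcomere protein gene, was 5.13-fold, Pygm 5.83-fold and Eno3 4.85-fold higher. The muscle list took 14.4% to 14.5% of the counts in the TSeL columns and 4.96%, 3.47% and 1.82% in the PBS samples. Whether the higher mitochondrial genes go with that muscle content was not tested, and 1 TSeL sample cannot separate them from it. Of 25 fatty acid oxidation genes 22 were higher, and 12 passed adjusted over the list alone (adjusted p = 0.455 with an estimated correlation), with Hadha 2.08-fold and Acaa2 2.19-fold higher.

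All 23 neutrophil genes had negative log2 fold changes in TSeL, with a median of -1.64, and 9 passed adjusted over the list alone (adjusted p = 0.334 with an estimated correlation). Trem1 was at 31.5 CPM and Cxcr2, the receptor of neutrophil-attracting chemokines, at 55.6 CPM, against 167 ± 21.5 and 189 ± 19.0 CPM in PBS (SD, n = 3). All 13 mast cell and basophil genes were lower, with a median of -1.60, and 8 passed adjusted over the list alone (adjusted p = 0.404 with an estimated correlation). The mast cell tryptase gene Tpsb2 was 3.42-fold lower. Of 27 chemokine genes 25 were lower, and 4 passed adjusted over the list alone (adjusted p = 0.334 with an estimated correlation); Cxcl12 was 3.17-fold and Cxcl5 2.60-fold lower. Of 24 cornified envelope genes 22 were lower, with a median of -0.82, and 3 passed adjusted over the list alone (adjusted p = 0.404 with an estimated correlation).

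The genes with the smallest p, none of which passed, were Neu2, S100a1 and Npr3, 4.19-fold, 2.50-fold and 4.06-fold higher, and Cyp1b1, Spink5 and Trem1, 4.93-fold, 2.92-fold and 5.31-fold lower, each with an edgeR adjusted p of 0.120. Spink5, a protease inhibitor of the epidermal barrier, was at 52.2 CPM in TSeL and 153 ± 7.75 CPM in PBS (SD, n = 3). By edgeR 0 genes changed, 3112 had an unadjusted p under 0.05, and the counts were 1354 by DESeq2 and 0 by limma-voom. The count was 417 with only TSeL and PBS in the fit, and 1315 without TL+L replicate 2, which enters through the shared spread. Camera called 29 lists, 10 higher and 19 lower, and none with an estimated correlation.

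The comparison of TSeL+L with PBS again rested on 1 treated sample. It showed lower neutrophil, chemokine and matrix degradation genes and higher hair genes, and 2 genes passed. Retnla (57262), an alternative-activation marker of macrophages, was at 20.7 CPM in TSeL+L and 1.88 ± 0.380 CPM in PBS, and rose with a log2 fold change of 3.46 (SE 0.26). Cxcl5 was at 13.6 CPM and 272 ± 21.4 CPM (SD, n = 3), a 19.9-fold fall; both had an edgeR adjusted p of 0.0424. Of 27 chemokine genes Cxcl5 alone passed over all genes tested and 8 adjusted over the list alone (adjusted p = 0.290 with an estimated correlation). Cxcl1 and Cxcl3 were 14.9-fold and 9.20-fold lower and did not pass (edgeR adjusted p of 0.0682 each).

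All 23 neutrophil genes were lower in TSeL+L, with a median of -2.53, and 17 passed adjusted over the list alone (adjusted p = 0.230 with an estimated correlation). Trem1 was 9.44-fold and Mmp9 8.42-fold lower. Of 17 matrix degradation genes 16 were lower, and 11 passed adjusted over the list alone (adjusted p = 0.230 with an estimated correlation). All 31 hair genes were higher, with a median of 4.60 (log2), or 8.07 without PBS replicate 3, and 8 passed adjusted over the list alone (adjusted p = 0.437 with an estimated correlation). Lef1 and Foxn1 were 13.2-fold and 7.85-fold higher, and Msx2, another transcription factor of the hair follicle, was at 66.5 CPM against 4.15 ± 3.89 CPM in PBS (SD, n = 3). Hair genes took 2.55% to 2.61% of the counts in the TSeL+L columns. Of 16 blood endothelium genes all were lower and 10 passed adjusted over the list alone (adjusted p = 0.564 with an estimated correlation), with Plvap, an endothelial membrane protein gene, 2.61-fold and Robo4 3.39-fold lower. Of 17 myofibroblast genes 9 passed adjusted over the list alone, all lower (adjusted p = 0.406 with an estimated correlation), with Thbs1, thrombospondin 1, 5.21-fold and Ccn2 3.06-fold lower. Of 12 melanocyte genes all were higher and 7 passed adjusted over the list alone (adjusted p = 0.437 with an estimated correlation).

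By edgeR 2 genes changed, with 3260 at an unadjusted p under 0.05; the counts were 1515 by DESeq2, 4 by limma-voom (Hdc and Trem1 besides these) and 1802 with only TSeL+L and PBS in the fit. The count was 0 without any 1 of the PBS samples and without TL+L replicate 1, 1 (Cxcl5) without TL+L replicate 3, and 2163 without TL+L replicate 2. Camera called 30 lists, 11 higher and 19 lower, and none with an estimated correlation.

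**Figure D3:**
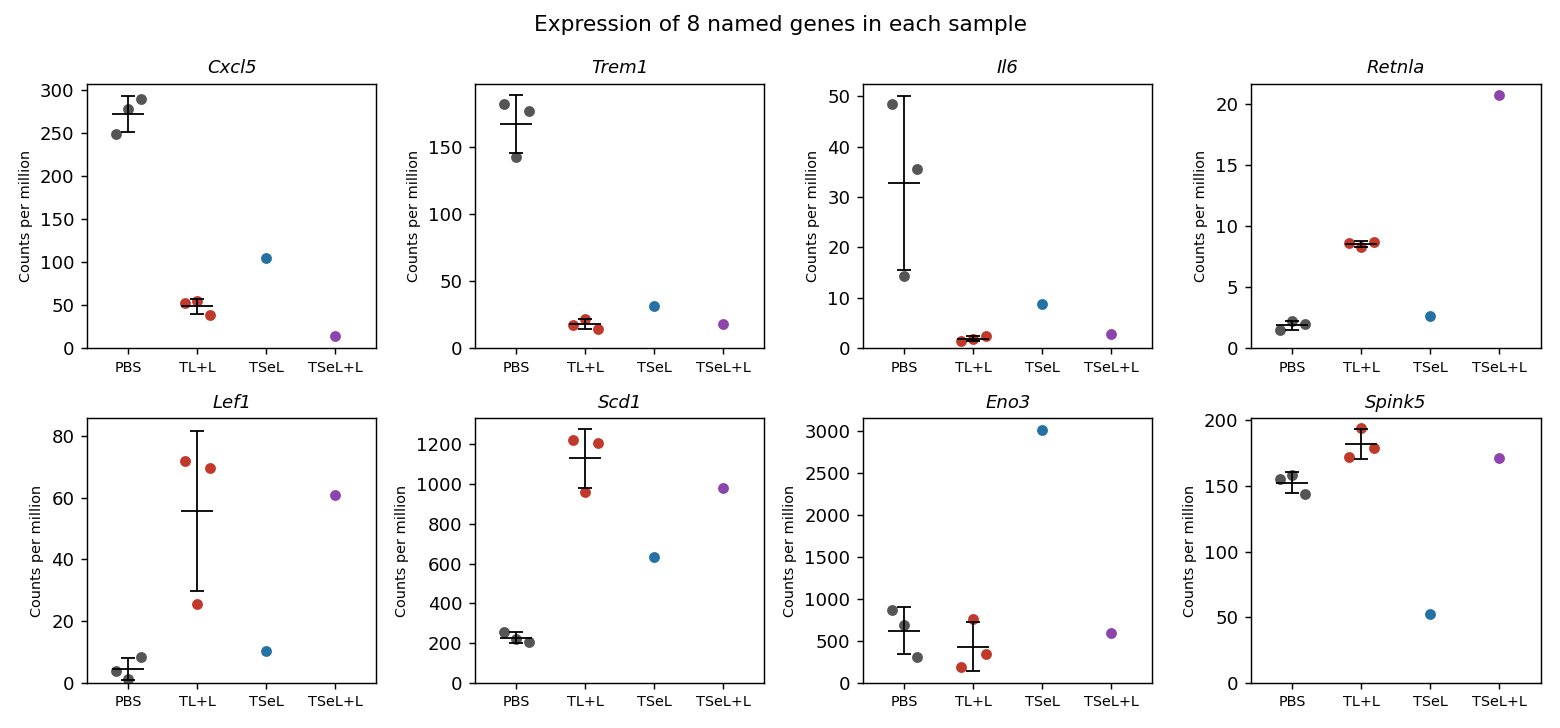
CPM (vertical axis, linear, from 0) of 8 named genes in each sample by group (horizontal axis); points are samples, and black bars give the mean and SD of the 3 PBS and 3 TL+L samples. Cxcl5 is lowest in TSeL+L at 13.6 CPM, Retnla highest there at 20.7 CPM, and Eno3 highest in TSeL at 3011 CPM.

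The fold changes of TL+L and TSeL+L, each against PBS, had a Pearson correlation of 0.926 across genes, which are not independent replicates, against 0.323 in 30 simulations of unchanged groups sharing the 3 PBS samples. Their covariance was 1.04, against 0.0920 simulated, a difference of 0.946. Both genes called in TSeL+L were called in TL+L in the same direction (1 higher and 1 lower, with 0.0567 and 0.0717 expected for independent lists). For TL+L and TSeL the correlation was 0.0237 (0.311 simulated) and the covariance 0.0250 (0.0924 simulated). For TSeL and TSeL+L these were 0.0426 (0.253 simulated) and 0.0455 (0.116 simulated), and with no calls in TSeL there was no overlap. The 3 PBS samples could not be split into parts of 2, so part of any excess may come from the shared controls. Hair list means were 5.98 to 9.11 log2 CPM in TL+L and 8.06 in TSeL+L, against -0.59 to 4.70 in PBS and 0.64 in TSeL. A hair level shared by TL+L and TSeL+L therefore cannot be told apart here from a shared effect of the treatments.

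TSeL+L and TSeL differ in their labels by the added L, with 1 sample each, so the difference has no replicate check and no p-value is given for a gene. Epidermal barrier and hair genes were higher in the TSeL+L sample, and mitochondrial, muscle and glycolytic genes lower. Muscle and oxidative phosphorylation list means in TSeL+L (9.86 and 6.92 log2 CPM) lay near the PBS means (9.81 and 6.80), with TSeL at 12.1 and 7.85. The cornified envelope mean was 4.69 in TSeL, 5.45 in PBS and 6.51 in TSeL+L. The hair list mean was 0.64 in TSeL and 8.06 in TSeL+L, and ran from -0.59 to 4.70 among the PBS samples. The added L cannot be told apart here from the muscle content of the TSeL sample, or from a difference in hair level between the samples. Medians were set against 10000 random lists of the same size matched on mean expression, as a description of these samples. Random genes were drawn singly, while list members can move together, so a median outside all 10000 is no test. The cornified envelope list had a median of 2.02, above all 10000; Cdsn, the corneodesmosin gene, was at 254 CPM in TSeL+L and 33.8 CPM in TSeL. The suprabasal differentiation list had a median of 1.89, above all 10000, with Dsg1a at 507 and 72.0 CPM. The level of Lce1g (16.4 and 2.80 CPM) and of Lce1a1 (56.6 CPM, 5.12-fold higher) is uncertain because their family holds near-identical copies. The hair list had a median of 8.14, or 7.91 with its 10 members that had no counts in TSeL set to a floor of 3 counts in that sample, and Padi3 was at 210 and 2.80 CPM. Krtap5-1 had 106 and 0 counts, at least 27.6-fold higher against that floor.

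The oxidative phosphorylation list had a median of -0.91, the skeletal muscle list -2.24, the hypoxia and glycolysis list -0.83 and the neutrophil list -1.21, each below all 10000 random lists. Cox6c was at 151 CPM in TSeL+L and 290 CPM in TSeL, Myh1, a fast myosin heavy chain gene, at 1733 and 10152 CPM, and Pgk1, a glycolytic enzyme gene, at 449 and 1305 CPM. The genes ranked first when the spread of the PBS and TL+L samples was assumed for both, which describes these samples and is no test, were Spink5, Pof1b and Calml3, 3.28-fold, 5.41-fold and 4.54-fold higher, and Cxcl5, Cebpd and Stbd1, 7.66-fold, 2.22-fold and 3.07-fold lower.

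TSeL+L and TL+L share the added L and differ in TSeL against TL, with 1 and 3 samples. Wound and hyperproliferation genes of the epidermis were lower in TSeL+L than the TL+L mean, and no gene passed. Their list mean was 5.36 log2 CPM in TSeL+L and 6.96, 6.02 and 5.48 in TL+L replicates 1, 2 and 3. Of 27 such genes 25 were lower, with a median of -0.94 (-0.47 without TL+L replicate 1), and none passed over all genes tested or adjusted over the list alone (camera adjusted p = 3.88e-19; adjusted p = 0.497 with an estimated correlation). Hbegf, a growth factor gene of the epidermal growth factor family, was at 27.9 CPM in TSeL+L and 56.8 ± 20.1 CPM in TL+L (SD, n = 3). Sprr2f was at 20.5 CPM, and at 164, 87.1 and 22.1 CPM in TL+L replicates 1, 2 and 3, and near-identical copies make its level uncertain. Il24 had 1 count in TSeL+L and 40 in the 3 TL+L samples, 13.4-fold lower with a 95% exact counting interval of 2.28 to 544. The Schwann cell and nerve list had a median of 0.53 (adjusted p = 0.497 with an estimated correlation), with the myelin gene Mbp 1.57-fold higher. The macrophage and monocyte list had a median of 0.26 (adjusted p = 0.564 with an estimated correlation), with Nos2 at 50.6 and 13.3 ± 8.78 CPM. The skeletal muscle list had a median of 0.59, or 1.42 without TL+L replicate 2 (adjusted p = 0.564 with an estimated correlation), and the complement and acute phase list 0.33 (adjusted p = 0.497 with an estimated correlation), with Ptx3 2.56-fold and Lbp 1.81-fold higher. The fatty acid oxidation list had a median of -0.34 (adjusted p = 0.564 with an estimated correlation), and its call was lost without TL+L replicate 2 (adjusted p = 0.631; 8.52e-22 to 0.995 over its 10 alternatives). Its member Ucp1 had 1 count in TSeL+L, and 817 of its 821 counts in TL+L came from TL+L replicate 2.

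The genes with the smallest p, none of which passed, were Retnla, Plaur and Slurp2, 2.43-fold, 2.06-fold and 2.13-fold higher, and Cxcl5, Il24 and Mmp9, of which Cxcl5 was 3.55-fold and Mmp9 2.30-fold lower. By edgeR 0 genes changed and 53 had an unadjusted p under 0.05; the counts were 1 by DESeq2 (Cxcl5) and 0 by limma-voom. Camera called 17 lists, 10 higher and 7 lower, and none with an estimated correlation; for the type 2 immune list, called higher with a mean of 0.13, the median was -0.01, and the call was lost without TL+L replicate 2 or 3 (adjusted p = 0.285 and 0.113; 0.0106 to 0.995 over its 10 alternatives). The adipocyte list, called lower (adjusted p = 0.0149; adjusted p = 0.961 with an estimated correlation), was called higher without TL+L replicate 2 (adjusted p = 0.00353; 1.59e-08 to 0.995 over its 10 alternatives). Without that sample 23 lists were called, 11 of them among the 17.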

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

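The fit of 12 columns was the planned one, and the fit of 8 samples reported here was chosen after seeing the data. The alternatives with 1 column per average, TMM without hair and muscle genes, samples left out where their group is not compared or for lists, and for lists the PBS and TL+L samples alone, were chosen after seeing the data. Counts of changed genes were within 1.5 times those reported under size factors of the DESeq2 type, library totals, no filter, the stricter filter, a 2-fold minimum, 1 column per average and TMM without hair and muscle genes, in all 5 comparisons. DESeq2 called 4064 genes for TL+L against PBS, 1354 for TSeL against PBS, 1515 for TSeL+L against PBS, 360 for TSeL+L against TSeL and 1 for TSeL+L against TL+L. Limma-voom called 4 for TSeL+L against PBS. With the planned 12 columns as separate samples, which treats near-repeats as replicates, these counts were 7164, 6521, 7093, 6618 and 3 (Retnla, Cxcl5 and Plaur). With only the compared groups, TSeL against PBS gave 417 and TSeL+L against PBS 1802; TSeL+L against TSeL then has no residual degrees of freedom and was not fitted. Leaving out 1 PBS or TL+L sample gave 16 to 6299 genes for TL+L against PBS, 0 to 1315 for TSeL against PBS and 0 to 2163 for TSeL+L against PBS, with each highest count without TL+L replicate 2; the other comparisons stayed at 0. The lone TSeL and TSeL+L samples cannot be left out. The counts for TSeL+L against TSeL, 1 sample each, borrow the spread of the other samples (or of the near-repeat columns) and are no replicated test. The cause of these moves was not tested. Leaving out TL+L replicate 2 gave higher counts with fewer samples in the 3 comparisons against PBS, so sample number alone cannot account for every move.

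PBS and TL+L samples share sample numbers. Deviations from the group mean of same-numbered samples correlated at -0.175, 0.130 and 0.212 across genes. Those of differently numbered samples correlated at -0.231 to 0.187. With 3 samples per group this can neither show nor exclude a pairing by number, and the labels state none. The fit with the number as a block (replicate block) held only the 6 PBS and TL+L samples and 15080 genes, and called 1066 genes for TL+L against PBS. The same samples without the block gave 2183, of which 940 were among the 1066. For lists the block gave 30 calls and the same samples without it 29, with 28 shared. PBS replicates 2 and 3 correlated best with their own number, and PBS replicate 1 did not. No paired analysis was possible because TSeL and TSeL+L are 1 sample each, wherever one of them is compared.

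With an estimated correlation 0 lists were called in each of the 5 comparisons. Fry, which asks whether a list's genes move one way, called 11 for TL+L against PBS, all among the 30, and 0 in the others. The named genes kept their direction in all 578, 351, 288, 345 and 364 values of the 5 comparisons under the alternatives that gave one. In TL+L against PBS 135 of these values lost the call, and in TSeL+L against PBS 9 did. A pseudocount was not varied because counts were tested.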

Other observations

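The count over splits of the samples was fixed before its result was seen; the tests of dilution, hair level, epidermal RNA and muscle were chosen after the results they bear on. Among lists not described above, barrier genes were higher in TL+L than in PBS: 3 of 24 cornified envelope genes rose (7 adjusted over the list alone), with a median of 0.71 (adjusted p = 0.436 with an estimated correlation). Of 22 cholesterol synthesis genes 3 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.591 with an estimated correlation). Of 26 cell death genes 10 fell and 1 rose (16 and 1 adjusted over the list alone; adjusted p = 0.396 with an estimated correlation). The selenoprotein list was not called: 4 of 26 genes fell and none rose, over all genes and adjusted over the list alone, with a median of -0.07 (adjusted p = 0.499). Of 27 NRF2 and antioxidant genes 5 fell and 2 rose (9 and 4 adjusted over the list alone), also without a call of the list (adjusted p = 0.348). With 1 sample left out, 0 to 7 cornified envelope and 0 to 17 cholesterol synthesis genes rose and 1 to 20 cell death genes fell over all genes tested, the most without TL+L replicate 2.

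The circadian clock list had a median of 0.60 in TSeL against PBS, with 2 of 18 genes higher adjusted over the list alone (adjusted p = 0.455 with an estimated correlation). Its call was lost without PBS replicate 3 (adjusted p = 0.0726; 0.00318 to 0.455 over its 10 alternatives). The Schwann cell and nerve list was higher there, with a median of 0.96 over 14 genes, none of which passed (adjusted p = 0.451 with an estimated correlation). In TSeL+L against PBS the wound and hyperproliferation list had a median of -1.58, with 1 of 27 genes lower adjusted over the list alone (adjusted p = 0.602 with an estimated correlation). PBS replicate 3 had an interferon response list mean of 5.93 log2 CPM, against 4.46 and 4.45 in the other PBS samples.

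Neutrophil genes were lower in TL+L. Only 1 of the 10 splits of the 6 PBS and TL+L samples, the real one, gave as many changed genes (2029, with 0 as the highest of the others); 10 splits are too few for a share under 0.05. Dilution of other transcripts by hair and muscle transcripts would shift all other genes by -0.03 (log2), whereas by library totals the neutrophil median was -2.61 (SD of its 23 members 1.11), which argues against it. A difference in hair growth phase was weighed with a linear model of the list mean: TL+L was lower by 2.90 without a hair term, and its effect was -1.72 (SE 0.399, 3 residual degrees of freedom) at a fixed hair list level, with a hair slope of -0.19 (SE 0.0559). Hair list means did not overlap between the groups (-0.59 to 4.70 log2 CPM in PBS and 5.98 to 9.11 in TL+L). The effect at a fixed hair level thus rests on an extended line and cannot decide whether hair level is the whole cause. That part or all of the difference goes with hair level stays open, and so does an effect of the treatment named by the labels.

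Hair genes were higher in TL+L, with a median of 4.72 (8.08 without PBS replicate 3). An overall gain of epidermal and follicular RNA would raise other lists of those tissues alike. The basal keratinocyte and follicle stem cell lists had medians of 0.05 and 0.97. Both lay below the hair median by more than the SD of its members (0.950), which argues against an equal gain in these lists in these samples. That SD is a spread between genes and does not measure the spread between samples. The melanocyte, sebaceous gland, cornified envelope and suprabasal lists had medians of 3.45, 1.78, 0.71 and 0.70, so a broader gain of unequal size stays open. Hair list means of only 0.95 and -0.59 log2 CPM in PBS replicates 1 and 2 also left room for large folds. Hair growth phase at sampling, which the labels do not give, and the treatment both stay open and were not tested for this pattern.

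Skeletal muscle genes were higher in the TSeL sample than in PBS: 100% of the list's measured members, 25 of 25, were above every PBS sample. More skeletal muscle in that piece of tissue and an effect of the treatment on muscle genes both predict this, so with 1 TSeL sample they cannot be told apart. All 25 also had counts in every PBS sample and none is in another list. Among the most abundant, Myh1 was at 10152 CPM against 2724 ± 1125 CPM and Ttn at 9345 against 1822 ± 781 CPM in PBS (SD, n = 3). The oxidative phosphorylation and fatty acid oxidation lists were also higher in the TSeL sample. Whether they go with its muscle content was not tested.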
